A study of Mus musculus with 4 samples.

How the data were processed

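Spatial gene expression was measured with the 10x Visium CytAssist assay, which captures gene-specific probes from a tissue section on an array of barcoded spots, in fresh-frozen mouse brain sections 10 µm thick. The 4 sections came from mice aged 10 months, 1 section per group: WT germ-free, WT colonised with Parabacteroides goldsteinii MTS01, LRRK2 G2019S germ-free, and LRRK2 G2019S colonised with Parabacteroides goldsteinii. The deposited count tables hold raw UMI counts per gene and spot, with the spots already filtered by the authors. The submitters' processing notes name Space Ranger 2.0.0 and the genome build GRCm38. The aligner settings, the probe set version and the annotation were not given in the sources used here. The tables list 19465 genes, and none of them is a gene of the mitochondrial genome. Spot positions and tissue images were not used here.

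Spots with fewer than 500 UMIs were left out, which removed 22, 2, 10 and 3 spots in the order of the groups above. Counts were scaled to 10000 per spot and log transformed, 2000 highly variable genes were chosen, and 30 principal components and 15 neighbours gave a joint Leiden clustering of all spots at resolution 1 (scanpy 1.11.5, igraph 0.11.9, seed 1). The 28 clusters were named after regions by 17 fixed lists of region markers. A name needed a mean z score of at least 1 over the list, a lead of 0.5 over the next list, at least 3 detected markers, and at least 1 marker among the leading genes. Other clusters kept their number. This rule was set after the clusters and their marker scores had been seen and before any comparison between sections. A spot holds RNA of several cells, so each name refers to a region and each share is a share of spots.

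The naming gave 24 region classes, and the 9 classes with at least 50 spots in every section were used. They held 55.7%, 56.0%, 54.1% and 56.3% of the clustered spots of the 4 sections. For each gene, CPM (UMIs of the gene scaled to a fixed total) was computed per class and section and averaged with 1 set of class weights, the mean share of each class over the 4 sections. The result is called standardised CPM below. The log2 ratio of 2 sections used a pseudocount of 1 CPM. A 95% interval was derived from the counts by the delta method, and the whole-section ratio of UMIs has an exact Clopper-Pearson interval. All intervals cover counting error only, and none covers the difference between mice or between sections.

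With 1 section per group no test between groups was made, and no p-value is given. Genes were counted by a size rule: a ratio of at least 1.5-fold, at least 10 standardised CPM in either section, at least 100 UMIs over the pair, and the same direction in every class in which the pair held at least 20 UMIs of the gene, with at least 3 such classes. Named genes were the 10 with the largest log2 ratio in each direction among the genes past this rule, leaving out Y-linked genes, fixed region markers and the 10 leading genes of each cluster; examples from a list were taken from its members with the largest ratios among those with at least 100 UMIs. For 40 fixed gene lists, the median log2 ratio over the measured members was set against 10000 random lists of genes matched in level in 20 bins. The percentile among these describes the list and is not a test. A list member was counted as higher or lower at 1.2-fold. The lists, the size rule, the naming of genes, the comparisons and most of the alternatives were fixed before the data were examined.

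The 4 comparisons were genotype in the germ-free pair, bacterium in the LRRK2 G2019S pair, bacterium in the WT pair and genotype in the colonised pair. In addition, the log2 ratio for the bacterium in the LRRK2 G2019S pair minus that in the WT pair was computed for genes and lists. The labels carry no replicate numbers, so no pairing was used. An additive model over both factors was not used, since it would assume that the bacterium acts alike in both genotypes. The alternatives were TMM factors (edgeR 4.0.16, R 4.3.3), whole-section CPM, equal class weights, other count filters, a pseudocount of 5 CPM, other minimum UMIs per spot, clustering resolutions 0.5 and 2, thinning of every spot to 3000 UMIs, and leaving out each class. Others were chosen after seeing the data: classes with enough spots in the pair alone, the midbrain dopamine class alone, leaving out the meninges class together with cluster 17, and lists without cluster-defining genes.

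The procedure was tested on simulated data for the 2 germ-free sections, with known folds in 50 genes per size. Both were given the class profiles of the WT germ-free section, and Poisson counts were drawn at each section's own class totals. No other difference between mice or sections was simulated, so the calls below cover counting error only. The size rule called 0 of 50 genes at 1.25-fold, 19 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, all in the right direction, and 0 of 10065 unaltered genes. The counting interval held the true value for 93.3% of genes. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.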

Results

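The data are spot-level gene expression from 4 mouse brain sections in a design of 2 factors. The first factor is the Parkinson disease allele LRRK2 G2019S, a point mutation that raises the activity of the kinase LRRK2, against wild type (WT). The second is colonisation of germ-free mice with the gut bacterium Parabacteroides goldsteinii. The WT germ-free section had 2970 spots and 53721818 UMIs, the WT colonised section 3348 spots and 53399643 UMIs, the LRRK2 G2019S germ-free section 3273 spots and 48298146 UMIs, and the LRRK2 G2019S colonised section 3061 spots and 58343993 UMIs. Each group has 1 section, so each difference below compares those libraries, not the conditions, and has no replicate check.

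Lrrk2 was read first. Its whole-section level was 27.1 CPM (exact 95% interval 25.7 to 28.5) in the WT germ-free section, 31.0 (29.5 to 32.5) in the WT colonised section, 27.6 (26.1 to 29.1) in the LRRK2 G2019S germ-free section and 26.2 (24.9 to 27.6) in the LRRK2 G2019S colonised section. A point mutation need not alter the transcript level, so these values say nothing about which allele a mouse carried. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in the LRRK2 G2019S germ-free section alone, at 46.3, 24.2, 38.4 and 47.0 CPM, with 0 to 3 UMIs of each in the other sections. That section therefore differs from the other 3 in Y-linked transcripts as well as in its group, in both comparisons that use it.

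The region classes were the upper and deep layers of isocortex, hippocampal CA1, the meninges, a midbrain class led by Slc6a3, Th and Slc18a2, and clusters 12, 14, 16 and 17, named by number. In the WT colonised section, hippocampal CA1 was made up mostly of cluster 4, where cluster 3 held it elsewhere. Cluster 13 took the place of cluster 5 in the midbrain dopamine class of that section, and cluster 11 joined cluster 1 in its upper isocortex. The meninges class joined cluster 8, with a mean z score of 3.56 for the meningeal markers, and cluster 20, with 1.29. Cluster 20 held 192 spots in the LRRK2 G2019S colonised section and 112 to 136 in the others. Clusters 4, 7, 11, 13, 23, 25, 26 and 27 held mostly spots of the WT colonised section.

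**Figure D1:**
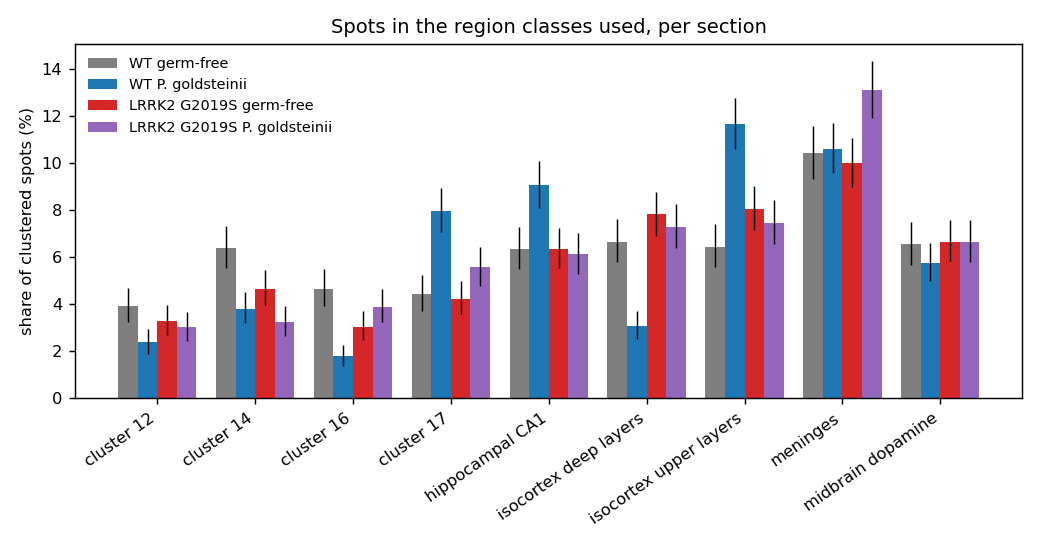
Share of clustered spots (%, y axis) in each of the 9 region classes used, for the 4 sections, with exact 95% intervals for counting error. The classes together held between 54.1% and 56.3% of the spots of a section.

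The genotype comparison between germ-free mice asked how the allele relates to brain expression in the absence of bacteria. Immediate early genes, which neurons transcribe within minutes of activity, were higher in the LRRK2 G2019S section, and Gbp4 and other genes of interferon-inducible GTPases, a family without a fixed list, were lower. Fos stood at 55.1 against 7.23 standardised CPM, a 6.82-fold ratio (log2 2.77, 2.53 to 3.01), and its whole-section ratio was 8.19 (exact interval 7.26 to 9.26). Nr4a1 was 3.98-fold higher at 112 against 27.5 CPM, and Dusp1 2.73-fold higher (log2 1.45). Of 20 measured immediate early genes, 15 were at least 1.2-fold higher and 0 lower, with a median log2 ratio of 0.76 (0.36 at clustering resolution 2 and 0.45 at a minimum of 50 CPM), at percentile 100 of matched random lists. Btg2, Junb and Npas4 were among them, with log2 ratios of 1.46, 1.22 and 1.82. The list's median was 1.41 in upper isocortex and 1.28 in deep isocortex, against 0.025 in cluster 17 and 0.26 in the midbrain dopamine class.

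Gbp4, which encodes a guanylate-binding protein, had the lowest ratio of the germ-free genotype comparison among named genes, at 4.12 CPM in the LRRK2 G2019S section against 21.8 in the WT section (log2 -2.15, -2.50 to -1.80). Gbp3, Gbp5, Gbp2 and Irgm2 had log2 ratios of -1.58, -1.04, -0.85 and -1.04. Xdh, H2-Q6, Pde1b, Scarb1 and Galnt15 were lower as well, at log2 ratios between -1.16 and -0.75. The fixed interferon list, which holds none of these genes, had a median of 0.083 with 4 of 14 members higher and 0 lower, so Ifit3 (log2 0.94) and Gbp4 went opposite ways. The other higher genes named by the size rule were Nbdy (111 against 38.2 CPM), Pcdh11x, Polr2k, Snrpn, Nfe2l2, Pcdhga3 and Dnase1l2, with log2 ratios between 0.63 and 1.52. In all, 21 genes were past the rule as higher, 4 of them Y-linked, and 15 as lower, of 10356. Over the alternatives the higher count ran from 8 to 42, and at a minimum of 50 CPM 0 lower genes were left. With the classes of the pair, lower genes outnumbered higher ones, 15 against 8, so the larger direction depended on the setting.

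Complement genes were higher in the LRRK2 G2019S germ-free section in 8 of 9 cases, with a median log2 ratio of 0.32 (percentile 100). This median was 0.16 with thinned spots and 0.12 over whole sections. C4b stood at 263 against 205 CPM and Serping1 at 31.7 against 23.5. Reactive astrocyte genes had a median of 0.26 (0.039 with thinned spots, 0.055 at a minimum of 50 CPM and 0.10 over whole sections). Vim stood at 227 against 149 CPM among 7 higher members, and Aspg and Gbp2 were the 2 lower ones. In the meninges the complement median was 0.63, with 10 of 10 genes higher, and it was 0.54 in cluster 12 (5 of 7 higher), 0.47 in cluster 16 (6 of 6), 0.30 in cluster 14 (5 of 6) and 0.14 in cluster 17 (5 of 6). It was 0.084 in upper isocortex (5 of 7), 0.0016 in hippocampal CA1 (3 of 6) and -0.037 in deep isocortex (3 of 6), and in the midbrain dopamine class 7 of 7 complement genes were lower, at -0.38. Without the meninges class and cluster 17, the complement median was 0.00088 and the reactive astrocyte median -0.10. Red blood cell genes were higher as well, 4 of 4, with a median of 0.90 and Hbb-bs at 960 against 496 CPM.

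Other medians outside the central 95% of random lists were found for 3 blood immune genes (0.53), cytokine and NF-kB genes (0.18, but -0.17 in the midbrain dopamine class alone) and heat shock genes (0.13, and 0.030 over whole sections) on the higher side. On the lower side were striatal projection neuron genes (-0.23), oligodendrocyte precursor genes (-0.19), dopamine neuron genes (-0.11, but 0.013 without a UMI minimum per spot and -0.41 without the midbrain dopamine class) and postsynaptic genes (-0.091, but 0.037 in that class alone). On the dopamine and striatal lists, 10 of 12 and 9 of 12 genes define a cluster. Homeostatic microglia genes had 0 of 12 members beyond 1.2-fold, activated microglia genes a median of 0.048, Parkinson disease genes -0.023 and genes of LRRK2 and its Rab substrates 0.017, all between the limits.

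The bacterium comparison in LRRK2 G2019S mice asked how colonisation relates to expression in carriers of the allele. Genes of mitochondrial respiration encoded in the nucleus were lower in the colonised section, synaptic genes were higher, and the complement and astrocyte genes named above stood lower. Ndufa2, a subunit of complex I, was at 87.3 against 247 standardised CPM, 2.81-fold lower (log2 -1.49, -1.56 to -1.42). Of 27 oxidative phosphorylation genes, 14 were lower and 2 higher, with a median of -0.28 at percentile 0, and Ndufa5 (90.7 against 206 CPM), Cox6c (162 against 350) and Cox8a (414 against 668) were among the lower ones. Atp5a1 and Atp5b were the higher members, with log2 ratios of 0.34 and 0.32. Outside the list, Timm8b (23.8 against 69.3 CPM), Atp5l (51.3 against 137), Uqcrh (62.4 against 147), Sdhaf4 and Tomm5, which also serve mitochondria, were lower by the size rule. Ranbp3l, Scrg1 and Polr2k were lower too, at log2 ratios of -1.46, -1.27 and -1.21.

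Presynaptic genes had a median log2 ratio of 0.28 in the LRRK2 G2019S pair, with 9 of 17 higher and 0 lower. Syn2 stood at 160 against 98.1 CPM and Sv2b at 238 against 156. Postsynaptic genes had a median of 0.23, with 9 of 19 higher and 1 lower. The scaffold genes Shank1 (156 against 80.6 CPM) and Shank3 (296 against 194) led them with Homer1 (155 against 106), and Dlg2 was the lower member. Nptx1 and Nptx2, which encode secreted pentraxins of excitatory synapses, were at 222 against 119 and 14.4 against 4.81 CPM. Gbp4 (12.6 against 4.12 CPM), Xdh, Creg2, Tesc, Cbl, Inafm1 and D630045J12Rik completed the higher named genes, with log2 ratios between 0.85 and 1.41. Immediate early genes were higher again, 14 of 20 with 0 lower, at a median of 0.31 (0.50 over whole sections and 0.030 in the midbrain dopamine class alone), but Fos itself differed little (60.5 against 55.1 CPM). Glucocorticoid response genes had a median of 0.29, with Cdkn1a, Sgk1 and Per1 at log2 ratios of 0.71, 0.65 and 0.50 and Sult1a1 lower at -0.65, and cholesterol synthesis genes 0.22 (0.015 at a minimum of 50 CPM). In the WT pair the presynaptic median was 0.15 (7 of 17 higher, 4 lower) and the postsynaptic one 0.18 (9 of 19 higher, 3 lower). Both lay between the limits.

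Complement genes were lower in the LRRK2 G2019S colonised section in 8 of 10 cases, with a median of -0.40. In cluster 17 they were higher (0.46, 6 of 7 genes), as were reactive astrocyte genes (0.50, 8 of 10), and in the midbrain dopamine class the complement median was 0.095. Reactive astrocyte genes had a median of -0.33 over the classes, with Vim at 133 against 227 and Cp at 27.8 against 48.1 CPM. Astrocyte identity genes had a median of -0.19 (-0.049 with thinned spots), with S100b at 274 against 474 and Aqp4 at 66.2 against 101 CPM. Meningeal genes were lower in 10 of 10 cases (median -0.62, Col3a1 at 19.1 against 36.7 CPM), red blood cell genes in 4 of 4 (-0.93), blood immune genes in 3 of 3 (-0.68, and -0.23 at clustering resolution 0.5) and interferon genes in 7 of 15 (-0.26). Dopamine neuron genes (0.20) and striatal projection neuron genes (0.32) were higher, but most of them mark a region class. The size rule held for 106 higher and 284 lower genes of 10419, the 4 Y-linked genes among the lower, and over the alternatives for between 56 and 169 higher and between 171 and 324 lower genes. Clustering at resolution 0.5 gave medians of -0.12 for complement, 0.014 for reactive astrocyte and 0.045 for meningeal genes, and the complement median was -0.058 without a UMI minimum per spot. Without the meninges class the complement median was -0.089, the reactive astrocyte one 0.033 and the interferon one 0.10, without that class and cluster 17 the complement median was -0.57, and over whole sections the dopamine neuron median was -0.35.

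The bacterium comparison in WT mice asked the same of mice without the allele. Immediate early genes were higher in the WT colonised section, and Gbp4 and Igtp were lower, together with many genes of large genomic length. Fos was 6.64-fold higher (53.7 against 7.23 standardised CPM), Nr4a1 4.52-fold (128 against 27.5), Npas4 3.80-fold, Dusp1 3.15-fold, Btg2 3.07-fold, Egr4 2.63-fold and Fosb 2.30-fold. Of the 20 immediate early genes, 19 were higher and 0 lower, with a median of 1.27 at percentile 100, and over the members with enough UMIs the median was at least 0.73 in each of the 9 classes. With 100 UMIs needed within the class, the midbrain dopamine class alone gave 0.66. Dusp4, Ier5 and Klc3 had log2 ratios of 1.10, 1.09 and 1.03. Igtp, another interferon-inducible GTPase gene, was at 4.36 against 19.8 CPM, and Gbp4 at 5.42 against 21.8. Fstl5, Kbtbd3, 9930021J03Rik, Glra3, Zfhx4, Zfp605, Mllt3 and Tenm1 were lower, with log2 ratios between -1.81 and -1.61.

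Circadian clock genes had a median of 0.23 in the WT pair, with Per1 at 122 against 71.8 CPM, Tef at 330 against 232 and Clock lower (log2 -0.72). Oligodendrocyte precursor genes had a median of 0.36, with C1ql1 and Olig2 higher (log2 0.96 and 0.61) and Pdgfra lower (-0.71). Cytokine and NF-kB genes had a median of 0.28, with Nfkbia higher (0.54) and Il18 and Vcam1 lower (-0.85 and -0.80). Red blood cell genes had a median of 0.66. Complement genes (-0.12) and reactive astrocyte genes (-0.10) lay between the limits, with Gfap higher (log2 0.61) and Gbp2 lower (-1.54). The median genomic length was 43925 bases among the lower genes and 16994 among the higher ones. Past the size rule were 270 higher and 1601 lower genes of 10387, but with TMM factors, which raised the median ratio of all genes by 0.14, there were 712 and 1061, so the higher share was 40.2% in place of 14.4%. Over the alternatives the counts ran from 174 to 712 higher and from 644 to 1913 lower genes. Without the meninges class and cluster 17 the red blood cell median was -0.42 and the cytokine median -0.017.

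The genotype comparison between colonised mice asked how the allele relates to expression in the presence of the bacterium. Fstl5, Mllt3 and 9930021J03Rik, lower in the WT colonised section than in the WT germ-free one, were higher in the LRRK2 G2019S colonised section than in that same WT section, and immediate early genes went opposite ways in different region classes. Fstl5 was at 23.3 against 6.46 standardised CPM (log2 1.70, 1.44 to 1.97), Mllt3 at 23.8 against 6.76 and 9930021J03Rik at 19.4 against 4.03. Clk4 (58.7 against 16.7 CPM), Cntnap5a (40.8 against 11.7), Diaph2, Gm4787, Snrpn, BC005561 and Arhgef6 were higher, with log2 ratios between 1.71 and 2.01. Slc2a4, which encodes an insulin-responsive glucose transporter, was at 14.0 against 33.1 CPM, and Mid1ip1 at 124 against 254. Nkx6-2 and Olig2, transcription factor genes of the oligodendrocyte lineage, had log2 ratios of -1.17 and -0.94. Col11a2, Gata2, Snai1, Tbx2, Nkd1 and Ndufc2 were lower, with log2 ratios between -1.07 and -0.87.

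In the colonised pair, Fos stood at 60.5 against 53.7 CPM, and the immediate early gene median was 0.023, with 4 of 20 genes higher and 3 lower. By class it was 0.35 in upper isocortex (18 of 20 genes higher), -0.36 in the midbrain dopamine class (11 of 14 lower) and -0.29 in hippocampal CA1 (14 of 20 lower). Hypoxia genes had a median of -0.33, with Bnip3, Ddit4 and Slc2a1 at log2 ratios of -0.65, -0.62 and -0.55. Red blood cell genes had a median of -0.73 and ependymal genes -0.58, and the genes of LRRK2 and its Rab substrates had a median of 0.19, between the limits, with Rab5a and Rab12 at log2 ratios of 0.83 and 0.62. Past the size rule were 1418 higher and 160 lower genes of 10386, and with TMM factors, which shifted the median ratio by -0.15, 917 and 498, a higher share of 64.8% in place of 89.9%. Over the alternatives the counts ran from 554 to 1751 higher and from 75 to 498 lower genes. Without the meninges class the red blood cell median was 0.14.

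The bacterium's log2 ratio in the LRRK2 G2019S pair minus that in the WT pair was highest for Gbp4 (3.23, from 1.41 and -1.83) among named genes. Gbp3, Igtp, Gbp5 and Irgm2 followed with differences of 1.85, 1.84, 1.83 and 1.67, together with Gm4787, Fstl5, 9930021J03Rik, Mllt3 and Pcdhb14. The lowest were Fos (-2.60, from 0.13 and 2.73), Npas4 (-1.82), Nr4a1 (-1.67) and Btg2 (-1.62). Ndufa2 had -1.39, from -1.49 and -0.094, while the oxidative phosphorylation list had a median of -0.074 (percentile 13.6), between the limits. The presynaptic and postsynaptic lists lay between the limits too, with medians of 0.059 (percentile 77.5) and 0.034 (percentile 63.9). Dusp1, Cebpb, Col11a2, Nkx6-2 and Sema3b had differences between -1.38 and -1.05. Of 38 lists with values, 12 lay below the central 95% of random lists, the sex-linked list (-5.34) among them, and 0 above. Immediate early genes had a median of -0.95, red blood cell genes -1.59, blood immune genes -0.79 (-0.030 over whole sections), hypoxia genes -0.31 and astrocyte identity genes -0.27. The medians of complement genes (-0.25), reactive astrocyte genes (-0.22), meningeal genes (-0.24), pericyte genes (-0.32), choroid plexus genes (-0.55) and ependymal genes (-0.56) all became positive over whole sections. Past the size rule were 1091 genes with a positive and 166 with a negative difference of 10554, and with TMM factors, which shifted the median by -0.14, 635 and 416, a positive share of 60.4% in place of 86.8%. Over the alternatives the counts ran from 482 to 1713 positive and from 101 to 416 negative.

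Across 10599 genes, the bacterium's log2 ratios in the 2 genotypes had a Pearson r of 0.41 (Spearman rho 0.43), and the 2 genotype ratios an r of 0.22 (rho 0.25). Genes are not independent replicates, so no p-value is given. The bacterium comparisons shared 26 genes past the size rule as higher, against 2.53 for independent lists, and 133 as lower, against 42.0. Shank1, Shank3, Inafm1, Mef2d and Kcnj4 were among the shared higher genes, Cox6c, Cox7b and Fabp7 among the shared lower ones, and Gbp4 and Brinp3 went opposite ways, 2 genes against 16.2. Except for Shank1 and Inafm1, these examples were chosen after their values were seen. The genotype comparisons shared Nbdy, Polr2k, Snrpn, Pcdhga3, Dnase1l2 and Zmat1 as higher, 6 genes against 2.19 for independent lists, and Six3 as lower, 1 against 0.153. Gbp4 and Igtp went opposite ways, 2 against 1.51.

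**Figure D2:**
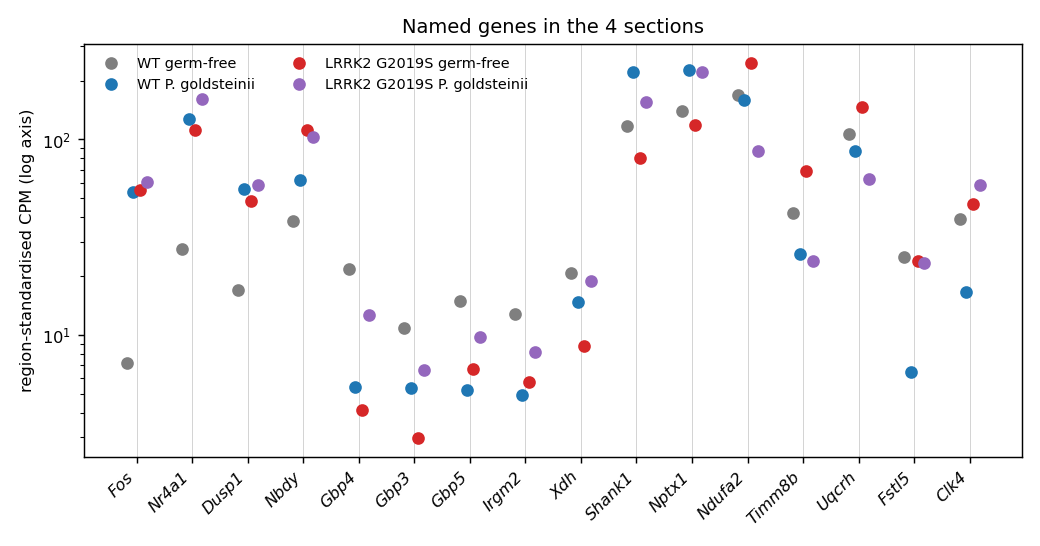
Standardised CPM (y axis, log scale) of 16 named genes in each of the 4 sections, 1 point per section. Fos stood at 7.23 in the WT germ-free section and between 53.7 and 60.5 in the other sections.

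**Figure D3:**
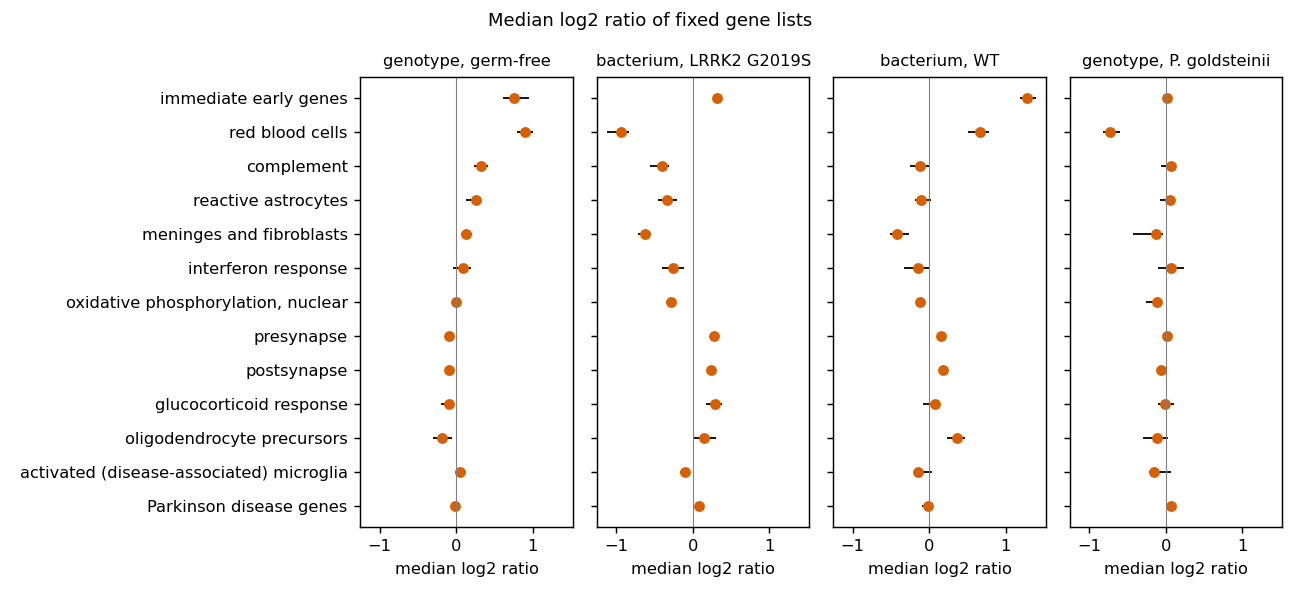
Median log2 ratio (x axis) of fixed gene lists (y axis) in the 4 comparisons, with bars for counting error. Immediate early genes lay at 0.76, 0.31, 1.27 and 0.023.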

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

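Several tests below were chosen after the result they measure was seen. These were the tests on the region make-up behind immediate early genes, on depth by class, on sex and on blood. The others were chosen after the patterns had been seen but before their own values were known.

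Red blood cell genes and Gbp4 went opposite ways in different pairs, and the difference was not tested. For the bacterium, the red blood cell median log2 ratio was -0.934 in the LRRK2 G2019S pair and 0.658 in the WT pair, and Gbp4 had 1.41 and -1.83. For the genotype, the red blood cell median was 0.901 in the germ-free pair and -0.731 in the colonised pair, and Gbp4 had -2.15 and 1.08. In standardised CPM, Hba-a2 and Alas2 went the same way as Hbb-bs in each pair. The red blood cell signs depend on the meninges class: without it the median was -0.39 in the WT pair and 0.14 in the colonised pair, and over whole sections 0.086 and 0.018. Over whole sections the genes went apart in the WT pair, colonised against germ-free: Hbb-bs stood at 226 against 263 CPM, Hba-a2 at 299 against 261, Hbb-bt at 3.35 against 2.51 and Alas2 at 7.10 against 7.20. In the LRRK2 G2019S pair Hbb-bs (247 against 520), Hba-a2 (308 against 434), Hbb-bt (3.12 against 4.37) and Alas2 (7.06 against 12.8) were all lower in the colonised section. Gbp4 was highest in the WT germ-free section (21.8 standardised CPM) and next highest in the LRRK2 G2019S colonised section (12.6).

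Immediate early genes were lower in the WT germ-free section than in each of the other 3, with Fos, Nr4a1, Npas4, Btg2 and Dusp1 among them. Sequencing depth is argued against in deep isocortex and stays open elsewhere. In that class the WT germ-free section was deeper than the LRRK2 G2019S germ-free one (median 23061 against 15119 UMIs per spot). It was shallower than the WT colonised section there (26618). The list was lower in it than in both, with class medians of 1.28 and 1.54 for the other section over it. With spots thinned to equal depth the median against the LRRK2 G2019S germ-free section was 0.758. CPM is already scaled to the total. Random thinning then mainly changes the weight of spots and the noise, so it could not decide this. Region make-up is argued against in deep isocortex, where the class median was 1.28. No list member was among the leading genes of that cluster. List members were not left out of the clustering, however, so deep isocortex need not be independent of them. The upper isocortex median was 1.41, but Egr1, Egr2, Egr3 and Arc were leading genes of its clusters. Upper isocortex therefore depends in part on the genes tested. Outside isocortex, region make-up stays open in the germ-free pair, with class medians of 0.0253 in cluster 17 and 0.26 in the midbrain dopamine class. The other classes there had 0.36 to 0.76. In the WT pair every class median, over the members with enough UMIs, was at least 0.73, which differing class shares alone would not give. Some classes of the WT colonised section were made up of other clusters, however. The allele, the bacterium and the state of a single mouse at sampling also stay open and could each contribute, since no second germ-free WT section exists here to tell them apart.

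Complement and reactive astrocyte genes such as C4b and Vim were higher in the LRRK2 G2019S germ-free section than in both sections it was compared with. Blood left in vessels stays open: the complement median of the WT pair was -0.125, but red blood cell genes were higher there only with the meninges class (0.66, against -0.39 without it), and the 2 lists went together in the germ-free pair (0.32 and 0.90) and the LRRK2 G2019S pair (-0.40 and -0.93). Both of the latter pairs hold the LRRK2 G2019S germ-free section, so they are not independent cases. Meningeal or pial tissue stays open in both comparisons. Against the WT germ-free section, the complement median was 0.000883 without the meninges class and cluster 17. Leaving out a class removes extra tissue and a difference within its spots alike, so this could not decide it. Clusters 12 and 16 alone gave 0.54 and 0.47 (reactive astrocyte genes -0.18 and -0.37). Cluster 17 scored highest for hippocampal CA1 and dentate gyrus (0.94 each), and no fixed meningeal marker was among its leading genes. In the LRRK2 G2019S pair the complement median was -0.57 without both classes and -0.089 without the meninges class alone. Sex cannot be told apart from the group, since the Y-linked genes, at 156 CPM in sum, were found in this section alone, and the allele in the germ-free state stays open, untested by replicates.

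Many genes, Fstl5, Mllt3 and Tenm1 among them, were lower in the WT colonised section than in the WT germ-free section, and its region make-up differed, with dentate gyrus at 0.30% of spots (3.66% to 4.44% in the other sections) and thalamus at 2.18% (0 spots in the others). The dentate gyrus share depends on the naming. Cluster 25 held 4.09% of spots in the WT colonised section and at most 0.92% in the others. It stayed unnamed because its scores for CA2 and CA3 (2.01) and for dentate gyrus (1.84) lay close. Depth is argued against as the whole cause. The WT colonised section was deeper than the WT germ-free one in upper isocortex (median 28289 against 21848 UMIs per spot). It was shallower in the midbrain dopamine class (8044.5 against 13676). The log2 ratios of these 2 classes still went together across genes, with a Pearson r of 0.679. After thinning, 3.81 lower genes per higher gene were left. CPM is already scaled to the total, so random thinning alone could not decide this. A different plane of cut stays open. The r of 0.679 between upper isocortex and the midbrain dopamine class argues against a shift confined to 1 of these classes. In the WT colonised section, however, cluster 13 held 191 midbrain dopamine spots and cluster 11 held 213 upper isocortex spots. Neither cluster had spots in the WT germ-free section. A shift in tissue shared by both classes could raise r as well, so r could not decide on the plane. That r was 0.188 in the germ-free pair and 0.381 in the LRRK2 G2019S pair. Library quality stays open and was not tested on its own: the WT colonised section had the lowest median genes per spot (4611, against 5069 to 5654), its 50 highest genes held 10.8% of UMIs against 9.12% to 9.17%, and its TMM factor was 0.927 against 1.02 to 1.03. A bias by gene length could contribute and cannot be told apart from a difference in long transcripts: Spearman's rho with genomic length was -0.241 here and 0.29 in the colonised pair, which shares the section, against 0.019 and 0.030 in the other pairs. Colonisation stays open. The bacterium's ratios agreed in part between genotypes, with r 0.41 and 133 shared lower genes against 42.0 for independent lists. Colonisation would still have to act more widely in WT mice, since 1601 genes were lower in the WT pair against 284 in the LRRK2 G2019S pair.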

How the results depend on the processing

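The settings with the classes of the pair, the midbrain dopamine class alone, the meninges class and cluster 17 left out together, and lists without cluster-defining genes were chosen after the results were seen. So was the choice of the complement, reactive astrocyte and immediate early gene lists, outside the random-list limits, as those whose every moved median is printed; other lists are printed where a median outside the random-list limits turned sign. The log2 ratios of named genes stayed within their counting interval in 1474 cases, moved beyond it in 176 and changed sign in 0. List medians stayed within it in 3364 cases and moved beyond it in 870, and medians outside the random-list limits changed sign in 56 more. Over all lists, those within the limits included, the sign differed in 475 cases. The oxidative phosphorylation median in the LRRK2 G2019S pair lay between -0.34 and -0.25 over 24 alternatives, the presynaptic one between 0.15 and 0.30, the postsynaptic one between 0.077 and 0.40 and the glucocorticoid one between 0.18 and 0.43. The immediate early gene median kept its sign in 24 of 24 alternatives in the germ-free, LRRK2 G2019S and WT pairs. TMM factors raised the median ratio of all genes by 0.14 in the WT pair and shifted it by -0.15 in the colonised pair and -0.14 in the difference. Values that moved follow, each with its comparison in parentheses. Over whole sections, genes past the size rule numbered 36 higher (germ-free genotype), 169 higher (LRRK2 G2019S bacterium), 412 higher (WT bacterium) and 1713 higher and 280 lower (difference). Pearson r was 0.44 (bacterium), and the list medians were reactive astrocyte 0.10 and complement 0.12 (germ-free genotype), dopamine neuron -0.35 and immediate early 0.50 (LRRK2 G2019S bacterium), cytokine -0.053 and immediate early 1.504 (WT bacterium), red blood cell 0.018 (colonised genotype), reactive astrocyte 0.22, complement 0.0052, pericyte 0.17, meningeal 0.35, choroid plexus 0.096 and ependyma 0.0026 (difference). With equal class weights, Pearson r was 0.27 (genotype) and 0.46 (bacterium). With TMM factors, genes past the size rule numbered 712 higher and 1061 lower (WT bacterium), 917 higher and 498 lower (colonised genotype) and 635 higher and 416 lower (difference). The list medians were immediate early 1.40 (WT bacterium). With 20 UMIs per pair and no minimum CPM, genes past the size rule numbered 36 higher (germ-free genotype). Pearson r was 0.17 (genotype) and 0.32 (bacterium). At a minimum of 50 CPM, genes past the size rule numbered 9 higher and 0 lower (germ-free genotype), 56 higher and 171 lower (LRRK2 G2019S bacterium), 174 higher and 644 lower (WT bacterium), 554 higher and 75 lower (colonised genotype) and 482 higher and 101 lower (difference). Pearson r was 0.25 (genotype) and 0.50 (bacterium), and the list medians were reactive astrocyte 0.055 and immediate early 0.45 (germ-free genotype), reactive astrocyte -0.48 (LRRK2 G2019S bacterium), immediate early 1.08 (WT bacterium). With a pseudocount of 5 CPM, genes past the size rule numbered 67 higher (LRRK2 G2019S bacterium) and 98 lower (colonised genotype). Pearson r was 0.43 (bacterium), and the list medians were immediate early 0.53 (germ-free genotype), complement -0.31 (LRRK2 G2019S bacterium), immediate early 1.10 (WT bacterium). Without a minimum of UMIs per spot, genes past the size rule numbered 34 higher (germ-free genotype). Pearson r was 0.26 (genotype) and 0.44 (bacterium), and the list medians were dopamine neuron 0.013 (germ-free genotype), reactive astrocyte -0.0091, complement -0.058 and interferon 0.029 (LRRK2 G2019S bacterium), reactive astrocyte 0.094, meningeal 0.30 and ependyma 0.20 (difference). At 2000 UMIs per spot, Pearson r was 0.31 (genotype) and 0.45 (bacterium), and the list medians were reactive astrocyte -0.039 and complement -0.16 (LRRK2 G2019S bacterium), reactive astrocyte 0.29, complement 0.12, pericyte 0.36, meningeal 0.52 and ependyma 0.12 (difference). At clustering resolution 0.5, Pearson r was 0.27 (genotype) and 0.46 (bacterium), and the list medians were reactive astrocyte 0.014, complement -0.12 and meningeal 0.045 (LRRK2 G2019S bacterium), reactive astrocyte 0.038 and meningeal 0.15 (difference). At clustering resolution 2, genes past the size rule numbered 33 higher (germ-free genotype). The list medians were immediate early 0.36 (germ-free genotype), reactive astrocyte -0.081, complement -0.21 and interferon 0.048 (LRRK2 G2019S bacterium), ependyma 0.27 (difference). With spots thinned to 3000 UMIs, genes past the size rule numbered 42 higher (germ-free genotype) and 691 higher (difference). Pearson r was 0.15 (genotype) and 0.34 (bacterium), and the list medians were reactive astrocyte 0.039 and complement 0.16 (germ-free genotype), immediate early 1.15 (WT bacterium). Without the meninges class and cluster 17, genes past the size rule numbered 36 higher (germ-free genotype). Pearson r was 0.29 (genotype) and 0.47 (bacterium), and the list medians were reactive astrocyte -0.10 and complement 0.00088 (germ-free genotype), complement -0.57, interferon 0.039 and immediate early 0.38 (LRRK2 G2019S bacterium), cytokine -0.017 and red blood cell -0.42 (WT bacterium), reactive astrocyte 0.28, complement 0.23, pericyte 0.51, meningeal 0.77 and choroid plexus 0.22 (difference). In the midbrain dopamine class alone, the list medians were reactive astrocyte -0.68, complement -0.43, cytokine -0.17, immediate early 0.26 and postsynaptic 0.037 (germ-free genotype), reactive astrocyte -0.053, complement -0.17, interferon 0.51 and immediate early 0.030 (LRRK2 G2019S bacterium), cytokine -0.29 and immediate early 0.66 (WT bacterium), reactive astrocyte 0.62, astrocyte identity 0.13, complement 0.95, pericyte 0.99 and meningeal 0.89 (difference). In that setting each member needed 100 UMIs within the class, so these medians can differ from the class medians given above. For lists without cluster-defining genes, the list medians were pericyte 0.14 (difference). With the classes of the pair, genes past the size rule numbered 8 higher (germ-free genotype) and 61 higher (LRRK2 G2019S bacterium). The 15 lower genes of the germ-free genotype then outnumbered the higher ones. Leaving out 1 class at a time gave 18 to 37 genes higher (germ-free genotype) and Pearson r of 0.19 to 0.31 (genotype) and 0.37 to 0.48 (bacterium). The list medians then ranged over reactive astrocyte -0.14 to 0.32, complement 0.0030 to 0.36 and immediate early 0.59 to 0.87 (germ-free genotype), reactive astrocyte -0.45 to 0.033, complement -0.56 to -0.089, interferon -0.44 to 0.10 and immediate early 0.27 to 0.37 (LRRK2 G2019S bacterium), red blood cell -0.39 to 0.77 (WT bacterium), red blood cell -0.78 to 0.14 (colonised genotype), reactive astrocyte -0.34 to 0.33, complement -0.34 to 0.19, pericyte -0.42 to 0.39, meningeal -0.36 to 0.74 and choroid plexus -0.57 to 0.29 (difference). A stricter CPM filter tests fewer genes by construction, and whole-section values drop the rule on agreement between classes; elsewhere the cause was not tested. Totals without mitochondrially encoded genes were not run, since the tables hold none. In data simulated at the depth of the germ-free pair, 19 of 50 genes at 1.5-fold, the fold of the size rule, and 49 of 50 at 2-fold were called; other depths were not simulated. Thinning left out 132, 182, 175 and 39 spots of the WT germ-free, WT colonised, LRRK2 G2019S germ-free and LRRK2 G2019S colonised sections.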

Other observations

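The prolactin gene Prl, chosen after its values were seen, stood at 9.25 CPM over the whole WT germ-free section (exact 95% interval 8.46 to 10.1) and at 1.75 (1.43 to 2.12) in the LRRK2 G2019S colonised section. The WT colonised section had 0.112 CPM, from 6 UMIs. The LRRK2 G2019S germ-free section had 0 UMIs, with an exact 95% upper limit of 0.0764 CPM. Prl is a hormone gene of the anterior pituitary, and no list of pituitary genes was fixed.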
